A study of Mus musculus with 6 samples.

How the data were processed

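Cerebral cortex of adult mice of the Htr4-EGFP/Rpl10a line ES1299 was profiled by translating ribosome affinity purification followed by RNA sequencing (TRAP-seq). In this line the ribosomal protein Rpl10a, fused to EGFP, is made under control of the Htr4 gene, which encodes a serotonin receptor. Per the labels' protocols, the dissected cortex was homogenised and tagged polysomes were captured with antibodies against EGFP on magnetic beads. The captured RNA is called IP here, and the RNA labelled as input is the reference. There were 3 input and 3 IP libraries, grouped by their titles.

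The deposited files hold raw counts of reads per gene symbol, with no normalization by the authors. Per the submitters' processing notes, reads were aligned with STAR 2.0.0e to the mouse build mm10 and HTSeq was used. The HTSeq version, its strand setting and the gene annotation are not given in the sources used here. Without a stated strand setting, reads of a gene cannot be told apart from those of an overlapping or antisense partner. HTSeq leaves out reads that align to several places, so genes with near-identical copies or pseudogenes, such as the ribosomal protein genes including Rpl10a, are counted with uncertainty. The files list 32531 gene symbols. Rows that name no gene were left out of library sizes and tests: reads outside annotated genes, reads matching several genes, reads aligned to several places, and a row called unknown with at most 2 reads. Their shares are given in the report. The list of mitochondrially encoded genes was fixed beforehand, but 0 of its 26 symbols are in the files.

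Reads on genes numbered 37696125, 50428338 and 52360452 in input replicates 1 to 3, and 53147173, 67559533 and 67080643 in IP replicates 1 to 3. The 3-read floor therefore lies between 0.0444 and 0.0796 CPM (counts scaled to a common library total). The exact 95% binomial interval of a category share is at most ±0.00959 percentage points wide on either side. Intervals and floors cover counting error only, since PCR reads are not independent molecules. Replicates were compared first: the chi-square per degree of freedom over genes ran from 22.0 to 65.2 between libraries of a group, so no 2 libraries were copies of each other.

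The main test was the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) on the deposited counts with TMM scaling, the filterByExpr filter, a group term alone, and a Benjamini-Hochberg adjusted p under 0.05, two-sided. This left 16506 genes. Fold changes are IP over input on the log2 scale, with standard errors (SE) derived from the test statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. Of the 31 gene lists fixed before the data were examined, 30 had at least 3 tested members. They were tested two-sided against all other tested genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Another 6 lists were added after the first results were seen and adjusted among themselves.

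The genes named are Htr4, Rpl10a and 7 marker genes, then the 10 genes with the largest positive and the 10 with the largest negative log2 fold change. Those 20 needed an adjusted p under 0.05, a mean CPM of at least 5 in the higher group and groups that did not overlap. Symbols of predicted genes (Gm and a digit, ending in Rik, or LOC and a number) were left out. Within each list the rule takes the 2 called members that moved most in the main direction, the 1 that moved most the other way and the most abundant member. Any member of the receptor, channel and layer lists may be named. Other genes are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

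The replicate number equals the sequencing lane in the labels for both groups, so each lane held 1 input and 1 IP library, and the number marks a shared lane. The deviations from the group means of same-numbered libraries correlated at 0.087, 0.061 and 0.043 across genes, against -0.057 to 0.0014 for differently numbered libraries. A fit with a replicate block was therefore run beside the main one. It called 3607 genes higher and 3966 lower. All inputs carried one library index and all IPs another, so index and group cannot be separated. The labels do not state that the replicates came from separate animals, or that an input and an IP of a number came from the same one. The p-values therefore measure only the spread between these samples, which may be technical.

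Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, total counts, TMM without ribosomal protein genes, no filter, a filter of at least 1 CPM in 3 libraries, the replicate block, and leaving out each library. For lists they also included an estimated correlation, fry, and members with a mean CPM of at least 5 only. Unlike camera, the rotation test fry asks whether a list changed at all, not whether it moved relative to the other genes. Added after seeing the data were protein-coding symbols only and offsets for transcript length and GC content, fitted as a loess trend per library with and without the block. The first offset was a mean-based trend, which shifted the log2 fold changes of its 14955 genes by a median of 0.24 against the main fit. A robust (symmetric) version was added for that reason. Lengths, GC content and coordinates came from GENCODE M21 (GRCm38, the assembly of mm10): 23113 symbols matched directly and 770 through a RefSeq synonym, while 8604 had no match.

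The procedure was tested on simulated data for IP against input over 16149 genes, 200 of them changed. It recovered 25 of 67 (37.3%) 1.5-fold, 40 of 67 (59.7%) 2-fold and 64 of 66 (97.0%) 4-fold changes, and called 10 unchanged genes. The changed genes had a mean of at least 1 CPM, with as many raised as lowered. In the data far more genes were called, and at least 2-fold 730 were higher and 2536 lower. The simulated shares therefore do not carry over to the data or to genes under 1 CPM. Scaling under such an imbalance was not simulated. Simulated unchanged lists passed an unadjusted p of 0.05 in 6 of 1000 cases. Genes were simulated independently of each other and drawn into these lists at random. This share therefore does not cover lists of correlated genes, such as the oxidative phosphorylation list (estimated correlation 0.66). Figures were drawn with matplotlib 3.10.9.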

Results

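The series compares RNA bound to EGFP-tagged ribosomes (IP, n = 3) with the input RNA (n = 3) of mouse cerebral cortex, in a line that tags ribosomes of cells with Htr4 promoter activity. Its stated subject is the transcriptional profile of pyramidal neurons. Input libraries held 37696125 to 52360452 reads on genes and IP libraries 53147173 to 67559533. Reads outside annotated genes made up 17.2% ± 0.722 of the listed reads in input and 8.78% ± 0.162 in IP (SD, n = 3). Reads matching several genes made up 8.99% ± 0.856 in input and 1.82% ± 0.0772 in IP. For each of these shares, the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The ribosomal RNA precursor symbol Rn45s took 2.20% ± 0.348 of gene reads in input and 4.29% ± 0.951 in IP. One symbol with a sequence number for a name, AK140265, took 12.1% ± 1.13 of gene reads in input and 0.193% ± 0.0528 in IP.

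IP differed from input at 7387 of 16506 tested genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 3523 were higher and 3864 lower in IP, and 9119 did not pass. Changes of at least 2-fold were more often decreases, with 730 genes higher and 2536 lower. The sign was the same within each of the 3 lanes for 3513 of the higher and 3855 of the lower genes. All IP libraries lay on one side of all inputs at 9252 tested genes (56.1%), where chance gives 10%. The first principal component of log2 CPM carried 73.8% of the variance and separated the groups. Group and library index coincide in this design. Of the 30 gene lists tested, camera called 8 higher and 8 lower in IP. With an estimated correlation, 1 and 5 of them were called.

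**Figure D1:**
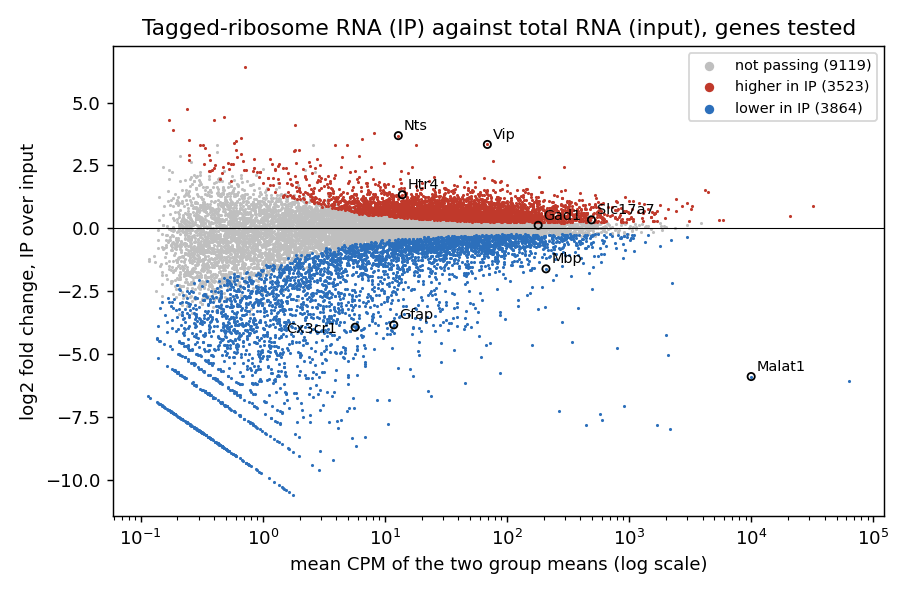
Log2 fold change of IP over input for each tested gene (y axis) against the mean of both groups' mean CPM (x axis, log scale). Red points are the 3523 genes higher in IP, blue the 3864 lower and grey the 9119 not passing. Parallel lines of blue points at the lower left are genes with few or no IP reads, whose fitted fold changes depend on the prior count. Circles mark named genes.

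Htr4, the gene whose promoter drives the tag, rose 2.52-fold in IP, from 7.88 ± 0.265 to 19.9 ± 2.36 CPM (log2 fold change 1.34, SE 0.16, adjusted p = 5.7e-05). Its log2 fold change was 1.19, 1.56 and 1.23 within lanes 1, 2 and 3. Htr4 lies on chromosome 18 at 62324204 to 62496577 on the plus strand (GRCm38). Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, had 435 ± 45.2 CPM in input and 549 ± 99.4 in IP (log2 fold change 0.34, adjusted p = 0.05005), just short of the threshold. With the replicate block it passed (adjusted p = 0.0052), and over all its alternatives the adjusted p ran from 0.00052 to 0.43. Camk2a, a kinase abundant in excitatory neurons, had 2850 ± 186 CPM in input and 3134 ± 677 in IP (log2 fold change 0.14, adjusted p = 0.41). Gad1, an enzyme of GABA synthesis, had 173 ± 16.3 and 188 ± 24.5 CPM (log2 fold change 0.12, adjusted p = 0.42). The astrocyte gene Gfap fell from 22.1 ± 3.73 to 1.55 ± 0.558 CPM, the myelin gene Mbp from 314 ± 28.8 to 103 ± 9.78, and the microglial receptor gene Cx3cr1 from 10.7 ± 1.10 to 0.701 ± 0.290. Their log2 fold changes were -3.84, -1.61 and -3.93. The endothelial gene Cldn5 had 4 to 19 reads per input library and 0 to 3 per IP library, too few for the test. Rpl10a, the tagged ribosomal protein, had 1.96 ± 0.605 CPM in input and 0.874 ± 0.106 in IP (adjusted p = 0.066). It was called lower in DESeq2 (adjusted p = 0.031), in limma-voom (adjusted p = 0.047), with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.045) and with the robust length and GC offset (adjusted p = 0.023, and 0.045 with the replicate block). It was covered by 45 to 132 reads per library and shares sequence with pseudogenes, so its value is uncertain.

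The genes that rose most included several neuropeptide genes. Neurotensin (Nts) rose from 1.88 ± 1.17 to 23.9 ± 9.62 CPM, vasoactive intestinal peptide (Vip) from 12.4 ± 1.02 to 126 ± 46.8, and the tachykinin genes Tac2 from 3.29 ± 0.312 to 32.6 ± 10.5 and Tac1 from 20.8 ± 5.82 to 134 ± 63.3. The other genes among the 10 highest were Tnnt1 (a troponin T gene), C1ql2, Tnfrsf13c, Clic6, Kcna5 (a potassium channel gene) and Isl1 (a LIM-homeodomain transcription factor gene). Log2 fold changes of the 10 ran from 2.69 for Tac1 to 3.79 for Tnnt1. Of the 10 genes that fell most, 9 carry sequence numbers as symbols and have no match in GENCODE M21. The exception is Gdap10, which fell from 13.7 ± 2.89 to 0.0444 ± 0.0399 CPM. The most abundant of the 10, DQ539915, fell from 4284 ± 830 to 17 ± 5.4 CPM (log2 fold change -7.98). Some had almost no IP reads: AK047804 had 779 input reads and 1 IP read, a ratio of the shares of 1111 with a counting interval of 198.8 to 43934.

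Markers of glia fell together. All 15 tested astrocyte genes fell (median log2 fold change -2.82), as did all 15 oligodendrocyte genes (median -3.68), all 14 microglial genes (median -4.14) and 7 of 8 oligodendrocyte precursor genes (median -3.12). The counts were the same adjusted over the list alone. Examples are the gap junction gene Gja1, from 36.2 ± 0.786 to 1.61 ± 0.830 CPM, the oligodendrocyte gene Ermn, from 131 ± 17.1 to 5.20 ± 0.794, and the purinergic receptor gene P2ry12, from 15.9 ± 0.386 to 0.558 ± 0.328. The exception, Lhfpl3, had a log2 fold change of 0.37 (adjusted p = 0.20). Camera called all of these lists lower, with a preset correlation (adjusted p = 3.2e-29, 9.6e-47, 2.2e-08 and 3.9e-06 in the order above) and with an estimated one (adjusted p = 0.0027, 0.0027, 0.023 and 0.036). Outside the glia, 8 of 11 endothelial genes fell (median -3.42, adjusted p = 0.027, and adjusted p = 0.32 with an estimated correlation), as did 3 of 4 blood genes (median -4.20, adjusted p = 0.020, and adjusted p = 0.32 with an estimated correlation). The endothelial receptor gene Tek had 165 input reads and 0 IP reads, 78.4-fold lower against a floor of 3 reads over the group. The lower end of the exact 95% counting interval of the ratio was 63.1-fold. With a filter of at least 1 CPM in 3 libraries, which left 3 of the 11 endothelial genes, the endothelial call ended (median -0.88, adjusted p = 0.19). Of 10 mural and fibroblast genes, 5 fell, and the list did not pass (adjusted p = 0.11). It passed without IP replicate 1 (adjusted p = 0.036), with the rotation test fry (adjusted p = 0.0067) and with the mean-based length and GC offset (adjusted p = 0.021, and 0.031 with the replicate block), but not with the robust one (adjusted p = 0.077).

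Neuronal markers rose in part. Of 15 pan-neuronal genes, 11 rose and 1 fell (median log2 fold change 0.48, adjusted p = 5.1e-05, and adjusted p = 0.21 with an estimated correlation). The calcium sensor gene Vsnl1 rose from 2388 ± 219 to 6455 ± 571 CPM and the neurofilament gene Nefl from 218 ± 29.1 to 571 ± 32.8, while the dendritic microtubule gene Map2 fell from 1243 ± 30.1 to 549.6 ± 33.4. Of 15 excitatory pyramidal genes, 4 rose and 3 fell (median 0.14, adjusted p = 0.52). Neurod6 rose from 169 ± 1.35 to 392.3 ± 43.7 CPM, and the zinc transporter gene Slc30a3 fell from 46.0 ± 3.14 to 31.3 ± 5.15.

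Genes of cortical layers went in different directions. Of 11 layer 5 pyramidal tract genes, 10 rose and 0 fell (median log2 fold change 0.96, adjusted p = 4.8e-10, and adjusted p = 0.018 with an estimated correlation). Fezf2, a transcription factor gene of subcerebral projection neurons, rose from 38.1 ± 2.81 to 136 ± 10.3 CPM, Pou3f1 from 15.8 ± 0.187 to 66.2 ± 13.7 and Bcl11b from 155 ± 12.6 to 270 ± 23.0. All 5 near-projecting genes of layers 5 and 6 rose (median 1.91, adjusted p = 0.00058, and adjusted p = 0.085 with an estimated correlation), among them Trhr, the receptor gene for thyrotropin-releasing hormone, from 5.45 ± 1.46 to 21.2 ± 5.02 CPM. Of 8 layer 6 corticothalamic genes, 5 rose and 2 fell (median 0.67, adjusted p = 0.070). The list passed without IP replicate 2 (adjusted p = 0.019), over members with a mean CPM of at least 5 (adjusted p = 0.027) and with fry (adjusted p = 0.014). Ntsr1 rose from 3.77 ± 0.782 to 10.9 ± 2.13 CPM. Of 6 layer 4 genes, 4 fell and 0 rose (median -1.22, adjusted p = 0.0048, and adjusted p = 0.12 with an estimated correlation). The nuclear receptor gene Rorb fell most, from 323 ± 52.7 to 34.9 ± 6.89 CPM. Of 11 layer 2/3 genes, 6 fell and 2 rose (median -0.47, adjusted p = 0.17, and adjusted p = 0.0017 with fry), with Stard8 falling from 42.1 ± 0.812 to 14.5 ± 3.37 CPM and Wfs1 rising (log2 fold change 0.78). The list median was -0.04 with the mean-based length and GC offset and -0.20 with the robust one, and the call of Cux1, its most abundant member, ended under both (adjusted p = 0.74 and 0.16, and 0.70 and 0.095 with the replicate block). The call of Wfs1 was lost without input replicate 3 (adjusted p = 0.058) and in DESeq2 (adjusted p = 0.067). Of the layer 5 intratelencephalic genes, 2 rose and 1 fell (adjusted p = 0.58), and of the layer 6b genes 1 rose and 1 fell (adjusted p = 0.84). A score of each library, the mean log2 CPM of 24 pyramidal tract, near-projecting and corticothalamic genes minus that of 17 layer 2/3 and layer 4 genes, was -0.69 ± 0.06 in input and 1.05 ± 0.11 in IP (two-sided exact permutation p = 0.1, the smallest possible).

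**Figure D2:**
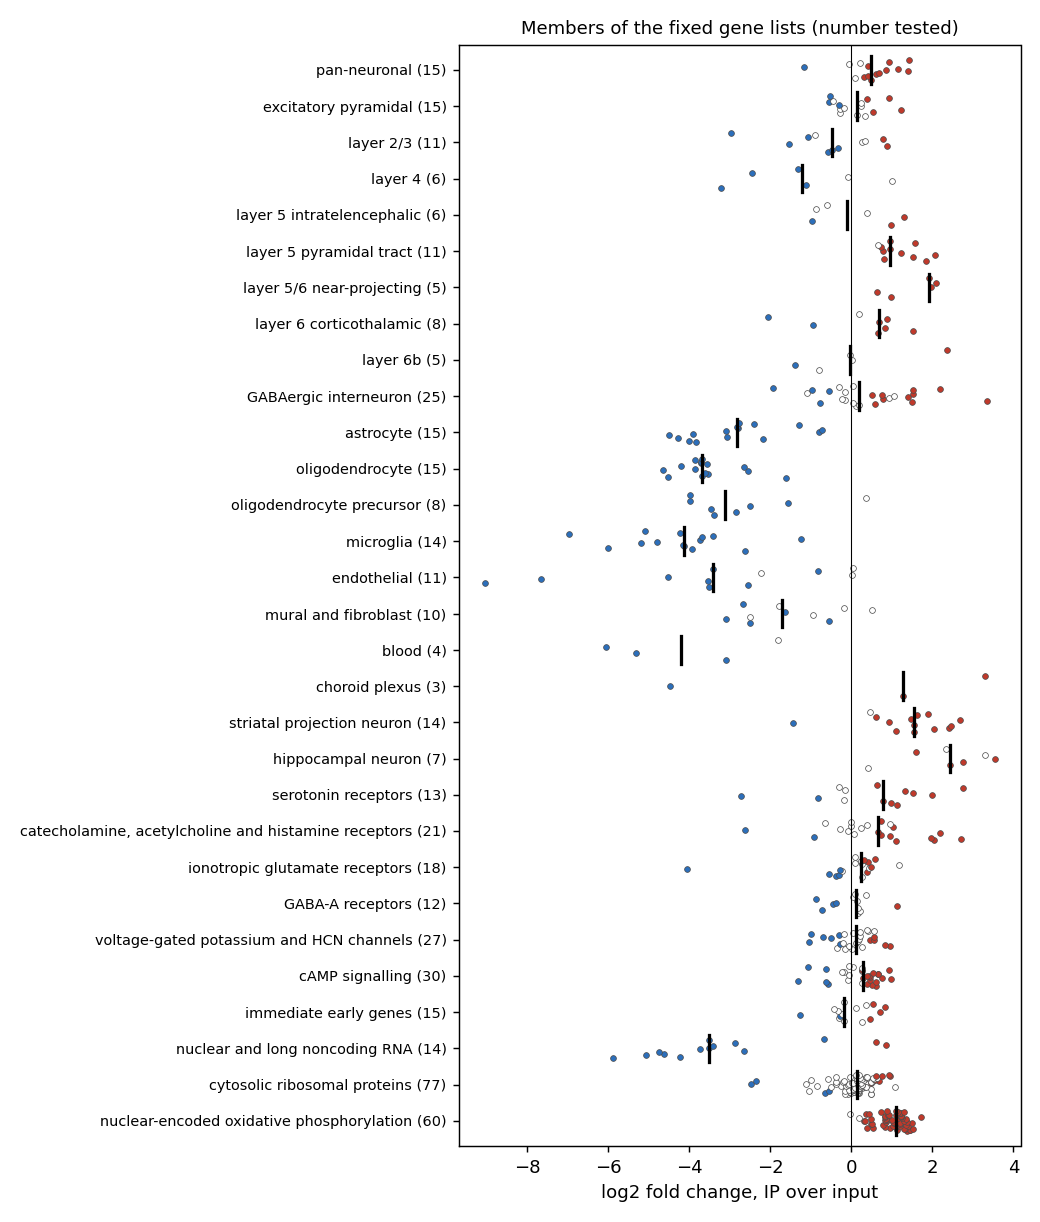
Log2 fold change of IP over input (x axis) for each tested member of the 30 lists fixed beforehand (y axis, number tested in brackets). Filled points passed an adjusted p under 0.05, red higher and blue lower in IP, open points did not pass, and black bars are medians. Medians of the astrocyte, oligodendrocyte and microglia lists lie at -2.82, -3.68 and -4.14, and that of layer 5 pyramidal tract at 0.96.

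Of 25 GABAergic interneuron genes, 10 rose and 4 fell (median log2 fold change 0.19, adjusted p = 0.094). With the replicate block the list passed (adjusted p = 0.042), as it did without IP replicate 2 (adjusted p = 0.0033), and the adjusted p ran from 0.0033 to 0.71 over its alternatives. Besides Vip, the calretinin gene Calb2 rose from 5.52 ± 1.78 to 25.1 ± 5.50 CPM, and the transcription factor gene Sox6 fell from 60.8 ± 5.98 to 15.8 ± 5.18. Of 14 striatal projection neuron genes, 12 rose and 1 fell (median 1.54, adjusted p = 1.4e-10, and adjusted p = 0.14 with an estimated correlation). All 14 had at least 1 CPM in input cortex, and Drd1, Drd2, Adcy5 and Pde10a are also in other lists fixed beforehand. The enkephalin precursor gene Penk rose from 90.2 ± 11.8 to 492 ± 85.5 CPM, and Rgs9 fell from 70.2 ± 14.3 to 26.1 ± 5.17. Of 7 hippocampal neuron genes, 4 rose and 0 fell (median 2.44, adjusted p = 0.088). Their median was 1.07, 3.27 and 0.71 within lanes 1, 2 and 3, and only 3 of them had a mean of at least 1 CPM in input. This list passed with the replicate block (adjusted p = 0.036, and 0.039 with the robust length and GC offset as well) and without IP replicate 3 (adjusted p = 0.0043), with a range of 0.0043 to 0.68 over its alternatives. Of 3 choroid plexus genes, Clic6 and Kl rose and Kcnj13 fell (adjusted p = 0.48). The call of Kl was lost without any 1 of the 3 input libraries (adjusted p = 0.087, 0.055 and 0.10 without replicates 1, 2 and 3), without IP replicate 2 (adjusted p = 0.18) and in limma-voom (adjusted p = 0.10).

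Among 13 serotonin receptor genes, 8 rose and 2 fell (median log2 fold change 0.78, adjusted p = 0.027, and adjusted p = 0.21 with an estimated correlation). Besides Htr4, Htr2c rose from 26.1 ± 6.43 to 104 ± 21.9 CPM, Htr5b from 0.711 ± 0.0675 to 4.85 ± 2.04 and Htr1a with a log2 fold change of 1.11, while Htr2a fell (log2 fold change -0.83). The list was not called with the mean-based length and GC offset (adjusted p = 0.090, and 0.097 with the replicate block, where the median was higher, at 1.04), and the call was kept with the robust one (median 0.63, adjusted p = 0.019). Without the block, the mean-based and robust offsets shifted their genes by medians of 0.24 and -0.11. Medians under the offsets therefore cannot be set directly against 0.78. Among 21 catecholamine, acetylcholine and histamine receptor genes, 10 rose and 2 fell (median 0.67, adjusted p = 0.045, and adjusted p = 0.30 with an estimated correlation). This call was also lost without input replicate 1 (adjusted p = 0.073), without IP replicate 3 (adjusted p = 0.058), with total counts (adjusted p = 0.061), with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.082) and with the length and GC offsets (adjusted p = 0.31 for the mean-based and 0.11 for the robust one, whose median was 0.32, and 0.26 and 0.10 with the replicate block). The dopamine receptor gene Drd2 rose with a log2 fold change of 2.05, and Adra1a fell with -0.91. Without Drd1 and Drd2, which are also in the striatal list, the list was not called (median 0.39, adjusted p = 0.17). Of the cAMP signalling genes, 16 of 30 rose and 5 fell (median 0.28, adjusted p = 0.025, and adjusted p = 0.30 with an estimated correlation). Its kinase subunit gene Prkaca rose from 215 ± 8.25 to 426 ± 41.8 CPM and the phosphodiesterase gene Pde10a from 192 ± 11 to 367 ± 23.2. The call ended with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.085), and without Pde10a and Adcy5, which are also in the striatal list (adjusted p = 0.078), where the median stayed at 0.27 and 14 of 28 genes rose. Both tests without striatal genes were added after the lists had been tested.

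The remaining neuronal families did not move as lists. Of 18 ionotropic glutamate receptor genes, 5 rose and 5 fell (adjusted p = 0.81). The median was 0.25 and the mean -0.06. Grin2c fell from 5.76 ± 0.188 to 0.349 ± 0.204 CPM and Gria2 from 967 ± 41.9 to 741 ± 33.0. Gria2 turned positive with a length and GC offset (log2 fold change 0.17, and 0.06 with the robust offset). Of 12 GABA-A receptor genes, 1 rose and 4 fell (adjusted p = 0.81, median 0.11, mean -0.01), with Gabra5 rising from 80.9 ± 4.17 to 176 ± 38.2 CPM and Gabra3 falling from 133 ± 9.03 to 80.0 ± 10. Of 27 potassium and HCN channel genes, 5 rose and 6 fell (adjusted p = 0.59). Kcnab1 rose from 73.1 ± 1.96 to 142 ± 5.95 CPM and Kcnc2 fell from 154 ± 21.6 to 74.1 ± 1.18. Of 15 immediate early genes, 4 rose and 2 fell (adjusted p = 0.78, median -0.18, mean 0.0045), with Nr4a3 rising from 9.21 ± 0.892 to 16.3 ± 3.93 CPM and Egr2 falling from 28.0 ± 6.77 to 11.7 ± 1.43.

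RNA classes also separated the groups. Of 14 nuclear and long noncoding RNA genes, 12 fell and 2 rose (median log2 fold change -3.52, adjusted p = 1.4e-28, and adjusted p = 0.0027 with an estimated correlation). Malat1, a nuclear noncoding RNA, fell from 19672 ± 4110 to 331 ± 142 CPM and Meg3 from 4042 ± 372 to 121 ± 29.3, while Peg13 rose from 348 ± 11.5 to 632 ± 63.6. Of 60 nuclear-encoded oxidative phosphorylation genes, 58 rose and 0 fell (median 1.10, adjusted p = 4.7e-26, and adjusted p = 0.25 with an estimated correlation). The median was 0.81, 0.98 and 1.46 within lanes 1, 2 and 3. The cytochrome oxidase subunit gene Cox5a rose from 46.6 ± 9.73 to 153 ± 20.4 CPM, while the most abundant member, the ATP synthase gene Atp5b, had 1144 ± 90.4 and 1118 ± 57.8 CPM (adjusted p = 0.79). Of 77 cytosolic ribosomal protein genes, 7 rose and 4 fell (median 0.15, adjusted p = 0.24). The list passed without input replicate 1 (adjusted p = 0.038), and its median ran from -0.30 with the robust length and GC offset to 0.32 over the alternatives. Adjusted over the list alone, the counts of the lists fixed beforehand were as given except in 9: 5 excitatory genes rose, 1 layer 4 gene rose, 2 layer 6b genes fell, 6 mural and fibroblast genes and 4 blood genes fell, 5 hippocampal genes and 11 catecholamine, acetylcholine and histamine receptor genes rose, 17 cAMP signalling genes rose and 6 fell, and 5 ribosomal protein genes rose and 3 fell.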

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

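Reads that aligned to several places, which enter no comparison of genes, made up 34.4% ± 1.43 of the listed reads in IP and 22.4% ± 1.21 in input (n = 3 each). This share drew attention because it was higher in IP than in the reference. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow.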

How the results depend on the processing

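The offsets for transcript length and GC content and the restriction to protein-coding symbols were chosen after seeing the data. Over the alternatives fixed beforehand, apart from leaving out a library, the count of genes higher in IP ran from 3184 to 4255 and that of genes lower from 3404 to 4710, against 3523 and 3864. Leaving out each library gave 2673 to 3418 higher and 3109 to 4095 lower genes, 598 to 906 and 2211 to 2876 of them at least 2-fold. It gave 8 to 10 lists higher and 8 to 9 lower. The replicate block gave 3607 and 3966 genes. Besides the calls of Slc17a7 and of the GABAergic and hippocampal lists given in the report, the block changed no call of a fixed list, and it ended the call of the dopamine receptor gene Drd3 (adjusted p = 0.0502). Total counts raised the median of all genes by 0.09.

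The offsets were fitted on the 14955 genes with a reference match. The 1551 genes left out held 50 of the higher and 756 of the lower calls. A refit on the 14955 genes without an offset, added after the counts under the offsets were seen, gave 3218 higher and 3332 lower genes, 631 and 1892 of them at least 2-fold. The mean-based length and GC offset gave 5578 genes higher and 2190 lower, and 5616 and 2242 with the replicate block. At least 2-fold it gave 1120 higher and 1514 lower, with 1513 lower under the block. Of its calls, 71.8% were increases, against 49.1% in the refit and 47.7% over all genes. This offset shifted the log2 fold changes of its genes by a median of 0.24 against the main result, and part of the change may be one of scale. The robust offset, with a median shift of -0.11, gave 2789 higher and 3202 lower genes. At least 2-fold it gave 352 higher, and 332 with the block. The cause of that decrease from the 631 of the refit was not tested. With an estimated correlation, camera called 1 list higher and 5 lower, against 8 and 8. A correlation above the preset 0.01 is not the whole cause. The layer 4 list, with an estimated correlation of -0.16, went from a camera adjusted p of 0.0048 to 0.12. The near-projecting list, at 0.0056, went from 0.00058 to 0.085. The other lists that lost their call had estimated correlations above the preset. What else differs between these settings was not tested.

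Gria2 reversed to 0.17 under the mean-based offset, both with and without the block, and to 0.061 under the robust one (0.060 with the block). Kcna2, at -0.15 and not called in the main result, was called at 0.37 (0.36 with the block) and at 0.24 (0.24 with the block). Of the 156 single genes followed, 145 had a value under every alternative fixed beforehand, and 125 of these kept their result throughout. Of all 156, 17 lost a call under at least 1, 9 gained one and 0 reversed. Depth left Cldn5, with at most 19 reads in a library, out of the test.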

Other observations

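The 6 lists of the next paragraph, the offsets for length and GC content, 2 tests (striatal tissue, and the loss of glial and vascular RNA, with its corrected gaps), and the layer difference over all deep lists were chosen only after results had been seen.

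Of 21 neuropeptide genes, 15 rose and 0 fell (median log2 fold change 1.03, adjusted p = 2.8e-09, and adjusted p = 0.065 with an estimated correlation). The list was written after Nts, Vip, Tac1 and Tac2 had been seen among the highest genes, so these 4 are no independent evidence of its direction. Of the other 17, 11 rose and 0 fell (median 0.63). The whole list was written after the first results, and 6 of its 21 members are also in lists fixed beforehand. The other 17 are therefore not independent evidence either. Sst rose with a log2 fold change of 1.49, Crh with 2.29 and Grp with 1.68, genes chosen after their values were seen. Genes of protein turnover and energy supply also rose, in lists that passed at the preset correlation but not with an estimated one (adjusted p = 0.19, 0.065, 0.19 and 0.065 in the order given): 27 of 31 proteasome subunits (median 0.58, adjusted p = 1.5e-08), 13 of 17 vacuolar ATPase subunits (median 0.64, adjusted p = 2.5e-06), 12 of 15 glycolysis genes (median 0.42, adjusted p = 0.0024) and 14 of 18 chaperonin and heat shock genes (median 0.46, adjusted p = 9.7e-05). No proteasome subunit fell, and 1 member of each of the other 3 lists did: Atp6v0e (log2 fold change -2.11), Eno1 (-3.39) and Hspa5 (-0.42). The pan-neuronal list had a median of 0.48, near those of these lists. Whether they rose beyond neuronal genes in general was not tested. Of 24 chromatin and splicing regulators, 14 fell and 2 rose (median -0.34, adjusted p = 0.00085, and adjusted p = 0.22 with an estimated correlation). With the robust length and GC offset the glycolysis and chromatin calls ended (adjusted p = 0.14 and 0.41), and the medians of the neuropeptide, proteasome and vacuolar ATPase lists were 0.67, 0.22 and 0.42 with their calls kept. The chromatin call also ended with the mean-based offset (adjusted p = 0.41), where its median was 0.04. Adjusted over the list alone, 16 neuropeptide, 29 proteasome and 13 glycolysis genes rose, and 3 chromatin and splicing regulators rose and 16 fell. The counts of the other 2 lists were as given.

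Fold changes followed transcript length. In the fifth of genes with the shortest transcripts the median log2 fold change was 0.38, with 1037 genes higher and 343 lower in IP. In the fifth with the longest it was -0.24, with 339 higher and 1102 lower. Across genes, which are not independent replicates, Spearman's rho was -0.25 with length and 0.14 with GC content.

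The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 3523 genes higher and 3864 lower, and the highest count of any other split was 0 in edgeR. In those 9 splits, 65 to 265 genes had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 at most 3. Each of them holds inputs and IPs in both groups, so the difference between input and IP becomes spread within the groups. Few calls follow from that alone, and no conclusion is drawn from them. The real split parts all 3 lane pairs, as do 3 of the others.

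The striatal projection neuron list was higher in IP. The tables argue against transcript length and GC content as its whole cause: its median of 1.54 stood at percentile 100 of 10000 lists matched on length, GC and expression, whose median was 0.33, and with the trend removed the median was 1.62, or 1.26 with the robust trend, with the camera call kept in both. That call rests on the preset correlation (adjusted p = 0.14 with an estimated correlation, before any offset). The mean-based and robust offsets shifted their genes by medians of 0.24 and -0.11, so 1.62 and 1.26 cannot be set directly against 1.54. Striatal cells in the dissected tissue remain a candidate explanation and cannot be told apart from cortical cells that use these genes. The range of the list's mean over the IP libraries lay at percentile 99.6 of 10000 expression-matched lists. Those lists hold genes drawn at random, while the striatal genes are correlated (estimated correlation 0.375). The percentile therefore cannot tell a variable carry-over from a variable share of cortical cells that use these genes. Rgs9 fell while 11 of the 12 members with at least 5 CPM in input rose. The abundant members Pde10a and Penk stood at 192 and 90.2 CPM in input. No biological explanation was tested.

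The pyramidal tract, near-projecting and corticothalamic lists of layers 5 and 6 together lay above the layer 2/3 and 4 lists by a difference of medians of 1.48. The layer 5 intratelencephalic and layer 6b lists, which did not pass (medians -0.11 and -0.04), are not in that difference, and with them it was 1.37 (permutation p = 0.0078). Among 10000 pairs of lists matched on length, GC and expression the difference stood at percentile 100, with or without those 2 lists, which argues against length and GC content as the whole cause. Striatal neurons also use Bcl11b, Crym and Foxp2, but without these 3 genes the difference was 1.53 (permutation p = 0.0014, 100000 resamples over genes, two-sided), and 1.37 with the 2 lists added (permutation p = 0.010). The difference therefore does not rest on these 3 genes. These permutations treat genes as independent and do not measure the spread between libraries. For the score per library, the two-sided exact permutation p was 0.1, the smallest possible. Whether striatal neurons use the other genes of the lists was not tested, so striatal cells as the source cannot be excluded. A higher share of tagged cells in the deep layers may account for the difference. That hypothesis was not tested, and index and group coincide.

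The nuclear-encoded oxidative phosphorylation list was also higher in IP. Its members are short, with a median transcript length of 1141 bases against 3402 for all tested genes, and matched lists had a median of 0.69. The list's median of 1.10 still stood at percentile 100 of 10000 matched lists, and it was 1.14 with the mean-based trend removed and 0.70 with the robust one, with the camera call kept in both at the preset correlation (adjusted p = 0.25 with an estimated correlation, before any offset). The mean-based offset shifted all its genes by a median of 0.24, and the robust one by -0.11, so 1.14 and 0.70 cannot be set directly against 1.10. Matched lists, at 0.69, also lay above the median of all tested genes, -0.015. Part of the rise therefore goes with length, GC content and expression. The draws could include the list's own genes, which may have raised the 0.69. How large that part is depends on the correction and stays open. A loss of glial and vascular RNA alone would leave it at or under the pan-neuronal list, and it lay 0.62 above that list (permutation p = 0.0014, 100000 resamples over genes, two-sided). With the length and GC trend removed the gap was 0.36 (p = 0.029), and 0.30 with the robust trend (permutation p = 0.049, with resampling error up to 0.0504, a bound added after that p was seen), and genes of the list are correlated, so that loss together with length cannot be excluded and stays open. The oxidative content of the tagged neurons, or a difference in RNA handling between input and IP, stays open and was not tested.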
